A study of Homo sapiens with 2 samples.

How the data were processed

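Total RNA from 2 cultures of the DLD-1 line, 1 transfected with a control siRNA and 1 with an siRNA against YY1, was converted to sense-strand cDNA and labelled with biotin for a whole-transcript GeneChip array, per the labels' protocols. The authors deposited 1 processed value per probe set and array. The software, background correction and normalization behind these values are not given in the sources used here. The deposited values were taken as log2 expression from the values themselves, which ran from 2.51 to 17.9, so the scale is inferred. The deposited medians were 6.86 for siControl and 6.93 for siYY1. Across the 25th, 50th and 75th percentiles the siYY1 array differed by 0.18, 0.07 and -0.13, so its values were more compressed, and the arrays had not been left with equal distributions.

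Groups were taken from the sample titles, 1 array each. By a rule fixed before the data were examined, the pair was quantile normalized because the percentiles differed by more than 0.05. Gene names came from a platform annotation table that named 1 gene symbol for 17709 probe sets and none for 3739, which are unnamed here and left out of the gene comparison. No probe set had several symbols. Symbols were updated through the gene ID to the RefSeq table of GRCh38.p14, which matched 17683 of 17687 genes. It was also the source of gene type and genomic span, and no coordinates are given because the build of the array design is not given in the sources used here. Values of the 20 genes with more than 1 probe set were averaged.

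The comparison used protein-coding genes whose higher log2 value of the 2 arrays was at or above the median of that value over all genes, which left 8747. The difference was siYY1 minus siControl in log2 units. With 1 array per group no test between conditions was possible, and genes were counted by size at 2-fold. The genes named in the text were, by the rule fixed beforehand, the 12 highest and 12 lowest, the 4 members farthest in the list's direction for each list outside the bounds, and up to 4 members past 2-fold in other lists. In addition, the text names members on the other side of a list's median, members near 0 and genes that set a range, chosen after their values were seen. YY1 itself was to be reported first, but none of the named probe sets was assigned to it.

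For each of 37 gene lists, written from general knowledge, the median difference of the members compared was placed among 10000 random lists of the same size drawn from the same 20 bins of mean log2 value. Lists with under 5 members were given as values. Medians within the outer 2.5% on either side were called outside the bounds, as a description of these 2 arrays. The result of 1 further list fixed beforehand is not reported here. In 4 of the 30 lists, none of them outside the bounds, the median and the mean had opposite signs. The lists for fibroblasts, leukocytes, endothelium and tissue-restricted genes served as background.

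The computation was tested on simulated data for this comparison. All 100 genes planted at a log2 difference of 1.5 and all 100 planted at 3 were recovered past 2-fold among 8744 genes. No unchanged gene passed 2-fold. The simulated noise was far below the SD of 0.75 across genes on the real arrays. This result checks the computation and gives no rate of false calls at 2-fold. The simulated lists held genes drawn at random, so they do not cover members that move together. Among 100 simulated lists of 20 genes, 2 without a shift were called, and 75 with a planted shift of 0.5, over 8747 genes. Alternatives tried were the values as deposited, centring on medians, loess on brightness, the brightest probe set, other brightness filters, thresholds of 1.5-fold and 3-fold, all gene types, list means and unmatched random lists. Random lists matched on gene span, removal of a gene span trend and lists without 2 members were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.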

Results

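The data were whole-transcript expression values from 2 microarrays of DLD-1 cells, an established human colorectal adenocarcinoma line. One culture had been transfected with a non-targeting control siRNA (siControl) and the other with an siRNA against YY1 (siYY1), each at 5 nmol/L, and RNA was taken after 3 days. YY1 is a zinc finger transcription factor that binds many promoters and enhancers. The question was which genes differ in level once YY1 is knocked down. Each group was a single array, so no difference below has a replicate error or a p-value, and the genes were ranked by the size of the log2 difference, siYY1 minus siControl. The differences compare these arrays, not the conditions. The values were taken as log2 from their range, since the scale is not given in the sources used here. The number of arrays limits the precision. A gene name was given here for 17709 probe sets, and the comparison used 8747 protein-coding genes whose higher value of the 2 arrays was at or above 7.50 on the log2 scale.

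The knockdown itself could not be read from the named probe sets: none of the 17709 was assigned to YY1, so the level of the targeted gene was not analysed here, and the group names rest on the labels. Of the 2 paralogs, ZFP42 was dim on both arrays and differed by -0.17, and YY2 was not among the named genes. The arrays correlated across genes with a Pearson r of 0.933 over the 8747 genes compared, which are not independent replicates. The differences had an SD of 0.75 across these genes, 0.81 in the dimmest of 3 equal parts and 0.66 in the brightest. Among 8498 protein-coding genes too dim to be compared the SD was 0.44. Of these 3.06% differed at least 2-fold, against 17.3% of the genes compared, so the spread did not grow steadily as values dimmed. As a measure of the noise in dim values, 16 dim genes restricted to other tissues ranged from -1.35 for MBP to 0.64 for MYL7. The list they belong to also held TNNI3, which was bright enough to be compared and was at 1.13. For 20 genes with more than 1 probe set, the differences of their probe sets lay a median of 0.38 apart and at most 0.98. Only 6 of these 20 were among the genes compared, so these values say little about that set.

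In the siYY1 array, 693 genes were at least 2-fold higher and 820 at least 2-fold lower, so that 45.8% of the 1513 were higher. The deposited values, used without further scaling, gave 536 higher and 1067 lower, or 33.4% higher. Over all genes compared, the median difference moved from -0.01 to -0.13 with that change, so the balance of the directions depended on the scaling.

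The lowest gene was NASP, a chaperone of linker and core histones, which was 9.57-fold lower in the siYY1 array (13.5 in siControl and 10.3 in siYY1, difference -3.26). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, was 8.37-fold lower at -3.07, a size that is uncertain because its siYY1 value was only 4.93. The splicing factor ESS2 was at -3.11 and FTSJ3, which acts in pre-ribosomal RNA processing, at -3.09. Also among the 12 lowest were TIMM8A, an import chaperone of the intermembrane space, at -3.01 and ETFDH, which passes electrons from fatty acid oxidation to ubiquinone, at -2.91. The immune checkpoint ligand CD276 differed by -2.87, CYB561 by -2.85 and TRIAP1, which acts in lipid transfer inside mitochondria, by -2.69. The last of the 12 lowest were ZNF664 at -2.64, the epithelial mucin MUC13 at -2.63 and TTC31 at -2.61. The siYY1 values of FTSJ3, CDKN1A, TIMM8A, CYB561 and TRIAP1 were at most 6.79, the highest value among 16 dim genes restricted to other tissues. The sizes and ranks of these 5 differences are uncertain, since background can hide a larger difference and noise can move it either way. These 16 genes leave out TNNI3, which was brighter. ETFDH, TTC31 and CD276, at 6.92, 7.41 and 7.43 in siYY1, were also below the brightness minimum of 7.50.

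The highest gene was RFX7, a transcription factor of the RFX family, which was 6.55-fold higher in the siYY1 array (8.40 in siControl and 11.1 in siYY1, difference 2.71). QSER1 followed at 2.59 and PTPN14, a phosphatase that restrains the growth regulator YAP, at 2.59. SIPA1L3, a GTPase-activating protein for Rap, differed by 2.56. CAD, which carries out the first steps of pyrimidine synthesis, was 5.52-fold higher, at 8.71 in siControl and 11.2 in siYY1. NPIPA3, NPIPB8 and NPIPA5 differed by 2.54, 2.42 and 2.42. They belong to 1 family of near-identical copies, so their probe sets can share signal and their values are uncertain as single genes. The 12 highest also held MSL1, the scaffold of a histone acetyltransferase complex, at 2.41, and CADPS, which acts in vesicle exocytosis, at 2.38. The last were CEMIP, which takes part in hyaluronan breakdown, at 2.35, and MARVELD1 at 2.34. A set of genes of large proteins was higher on this array. It was drawn from 250 gene symbols, chosen after the values were seen, and no lengths were measured. Members of the fixed lists, the gene families chosen after the values were seen and the 30 largest differences either way were left out. Over the 158 genes used, the median was 0.67, with 59 at least 2-fold higher and 3 at least 2-fold lower. Whether protein size accounts for the 12 highest genes, which this set leaves out, was not tested.

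**Figure D1:**
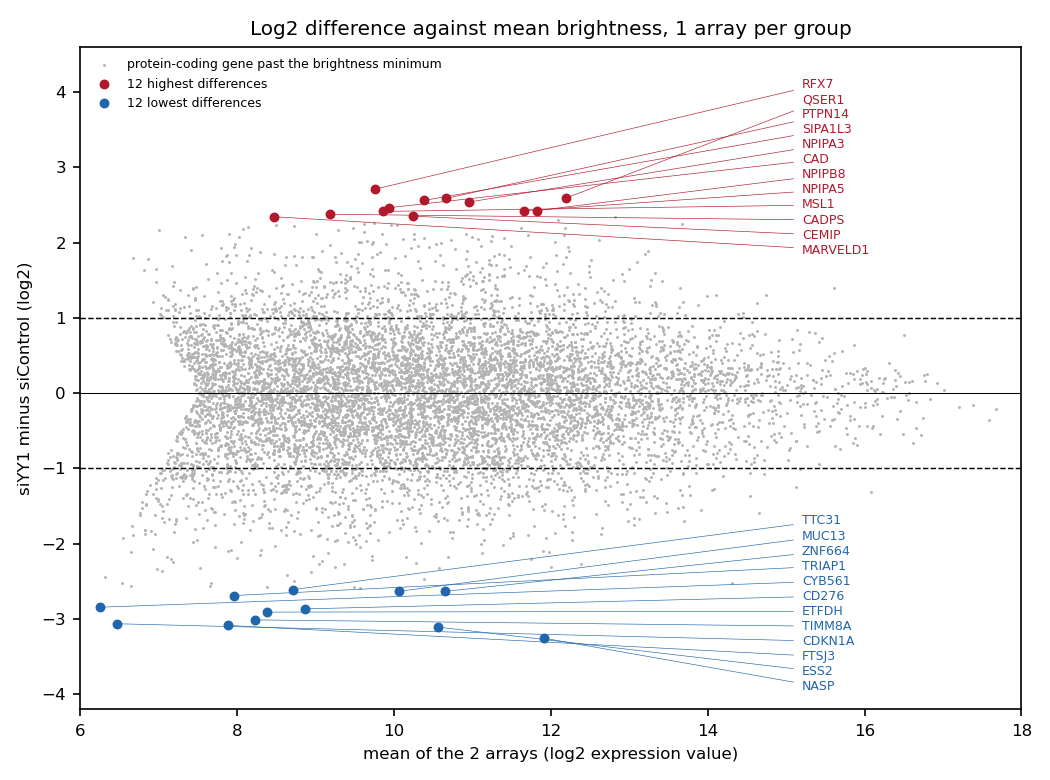
Log2 difference (siYY1 minus siControl) against the mean log2 expression value of the 2 arrays for the 8747 genes compared, each point 1 gene, with dashed lines at 2-fold. The 12 highest genes, in red, lie between 2.34 and 2.71, and the 12 lowest, in blue, between -2.61 and -3.26.

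Gene groups were compared through 37 lists fixed before the data were examined. Of these, 30 had at least 5 members among the genes compared, and each median was placed among the medians of 10000 random lists of the same size and brightness. Within the lowest 2.5% of the random medians lay 2 lists and within the highest 2.5% lay 1. Of 30 lists of genes drawn at random, about 1.5 would lie outside these bounds. Members of a pathway can move together between any 2 cultures, so this is not a chance rate for such lists. The 3 lists shared no member among the genes compared.

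Genes of glycolysis and of the response to low oxygen were lower as a group in the siYY1 array. The median of the 24 members was -0.69, a 1.62-fold lower level and below all 10000 random lists, of which all but the outer 2.5% on each side ran from -0.28 to 0.25. In all, 22 members were lower and 5 of them at least 2-fold. EGLN3, an oxygen-sensing hydroxylase that is itself induced by hypoxia, was 4.62-fold lower at -2.21. Its siYY1 value of 6.05 was in the range of dim genes restricted to other tissues, so this size is uncertain. LDHA, which converts pyruvate to lactate, was at 16.7 in siControl and 15.4 in siYY1, a difference of -1.32. PFKP, the platelet form of phosphofructokinase, differed by -1.29 and P4HA1, a collagen prolyl hydroxylase, by -1.18. The members above 0 were PFKL at 0.68 and KDM3A at 0.40. GAPDH, at 17.5 and 17.3, differed by -0.16.

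The list of cholesterol and fatty acid synthesis held members on both sides. The 25 members had a median of -0.50, at percentile 0.10, with 3 at least 2-fold lower and 1 at least 2-fold higher. The 4 lowest were enzymes of the mevalonate and sterol pathway: IDI1 was 4.94-fold lower at -2.30, FDPS differed by -1.54, MVD by -1.23 and MSMO1 by -0.94. The regulator SREBF2, a transcription factor that drives these enzymes, was 3.60-fold higher at 1.85. Other values above 0, named after their values were seen, were SREBF1, just under 2-fold higher, the fatty acid enzymes ACACA at 0.96 and FASN at 0.87, and the sterol enzymes SC5D at 0.27, NSDHL at 0.25 and SQLE at 0.24. The fatty acid enzymes SCD at -0.91 and ELOVL6 at -0.54 were below 0, so neither branch lay on a single side. The set of genes of large proteins given above was higher on this array. Whether protein size accounts for the levels of SREBF2, SREBF1, ACACA and FASN was not tested. The list's place outside the bounds did not hold without its 2 lowest members, when the median was -0.17 at percentile 13.6, or among genes past the 75th percentile of brightness, also -0.17, at percentile 13.8.

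Genes of the microRNA and RNA interference machinery were higher in the siYY1 array. All 9 members compared were above 0, with 5 at least 2-fold higher, and their median of 1.13 (2.19-fold) lay above all 10000 random lists. The Argonaute genes AGO2 and AGO1 were at 1.59 and 1.38, and AGO3 was at 0.15. TNRC6B, a partner of Argonaute in silencing, was at 1.54 and DROSHA, the nuclear microRNA-processing nuclease, at 1.29. Both arrays received the same dose of an siRNA. The set of genes of large proteins from outside the lists, chosen after the values were seen, was higher too. Its 158 genes had a median of 0.67, with 118 above 0. Genes in the tenth with the widest genomic spans had a median of 0.22, against 0.00 in the narrowest.

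**Figure D2:**
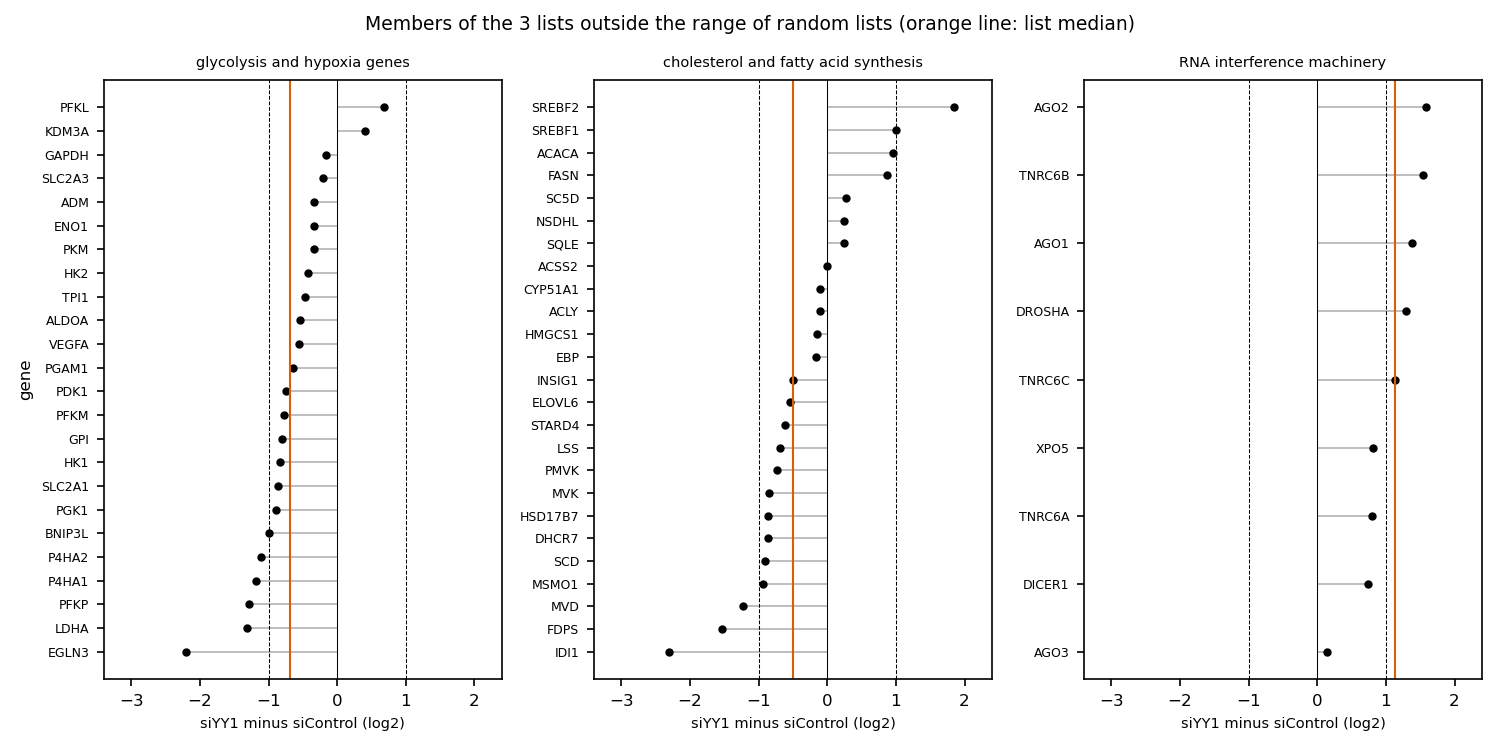
Log2 difference (siYY1 minus siControl) of each member compared in the 3 lists whose medians lay outside the range of random lists, each point 1 gene, with the list median in orange and dashed lines at 2-fold. Only PFKL and KDM3A lie above 0 among the 24 glycolysis and hypoxia genes, SREBF2 is the only one of 25 cholesterol and fatty acid genes past 2-fold on the higher side, and all 9 RNA interference genes lie above 0.

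Cell cycle genes had medians below 0, inside the range of random lists in the main setting. S phase genes had a median of -0.24 over 33 members, at percentile 4.80, with 5 at least 2-fold lower and 1, SLBP at 1.01, at least 2-fold higher. The list was outside the bounds at percentile 1.94 without a brightness filter and at 0.45 with list means. Among the lower ones the replicative helicase subunit MCM5 was at -1.47, the uracil glycosylase UNG at -1.24, CDCA7 at -1.13 and the primase PRIM1 at -1.11. For 46 G2/M genes the median was -0.14, at percentile 8.78, with 4 at least 2-fold lower and 2 at least 2-fold higher. Here the cytokinesis factor ECT2 was at -1.87, HMMR at -1.46 and CDC20 at -1.11, while CENPF was at 1.22. Replication-dependent histone genes had a median of 0.02 over 37 members, and only H1-5, at -1.06, passed 2-fold. DNA repair genes had a median of -0.30 at percentile 5.65, with LIG1 at -1.26, XRCC5 at -1.23 and XRCC2 at -1.04, and the median was -0.18 at percentile 18.1 without its 2 lowest members and -0.61 at percentile 0.61, outside the bounds, with only genes past the 75th percentile of brightness.

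Mitochondrial gene groups held members far from 0 on both sides. Complex I subunits had a median of 0.27 over 32 members, at percentile 97.1 and outside the bounds at 99.1 with random lists matched on gene span too, with NDUFA13, NDUFC1 and NDUFV2 between 1.02 and 1.06 and NDUFV1 at -1.15. In the values as deposited the 3 higher ones were below 2-fold. Subunits of complexes II to V had a median of 0.15, and the 3 past 2-fold were all lower: SDHC at -1.60, ATP5F1A at -1.59 and ATP5F1D at -1.17. Among 71 mitochondrial ribosomal protein genes the median was -0.02, with 6 at least 2-fold higher and 2 at least 2-fold lower. MRPL49 was 5.55-fold lower at -2.47 and MRPL2 was at -1.80, while MRPL48 was at 1.69 and MRPL50 at 1.34. The 45 cytosolic ribosomal protein genes had a median of 0.06 and none passed 2-fold. Proteasome subunits were centred at 0.0031, with PSMB5 at -1.42 and PSMC4 at -1.37.

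Complexes that act with YY1 on chromatin lay within the range of random lists in the main setting. The INO80 remodelling complex, of which YY1 is a known partner, had a median of 0.04 over 13 members, with INO80D at 1.84 as its only member past 2-fold. Polycomb genes had a median of 0.15 over 19 members, none past 2-fold. Cohesin and loop anchor genes had a median of 0.40, at percentile 96.4, and were outside the bounds at 98.6 with list means and at 97.7 with a gene span trend removed. The list was inside at 92.3 with random lists matched on gene span too, and at 94.4 without its 2 highest members. Among them the cohesin loader NIPBL was 4.33-fold higher at 2.11 and the Mediator kinase module subunit MED12 was at 1.60. Both encode large proteins, and the set of such genes from outside the lists was higher too, with the median of 0.67 given above.

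Stress and metabolic programmes other than those above were within the bounds in the main setting. The ATF4 and unfolded protein response list had a median of -0.24 at percentile 4.38, and its members past 2-fold were DDIT4 at -1.78, CARS1 at -1.39 and PHGDH at -1.04. For the pentose phosphate pathway and NRF2 targets the median was -0.32 at percentile 4.82, with PGD at -1.96, TXNRD1 at -1.71 and GCLM at 1.15. With only genes past the 75th percentile of brightness that median was -0.54 at percentile 0.64, outside the bounds, as it also was at percentile 1.43 without a brightness filter and at 2.25 with a gene span trend removed. Ribosome biogenesis and MYC target genes had a median of -0.16, with 4 at least 2-fold lower and 1 at least 2-fold higher, where NOP2 was at -1.54 and NOP16 at -1.33 while CAD was among the highest genes of all. Heat shock and chaperone genes had a median of -0.05 with none past 2-fold. Splicing factors had a median of -0.07, with SF3B2 at -1.33, SRSF1 at -1.25 and PRPF4 at -1.06.

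Signalling and immune groups gave medians within the bounds too, in the main setting. Interferon-stimulated genes, which double-stranded RNA can induce, had a median of 0.09 over 17 members, with HERC5 at 1.11, while IFI6 was 2-fold lower. Class I antigen presentation genes had a median of -0.40 at percentile 4.64, with ERAP1 at -1.13, and -0.20 at percentile 22.3 without the 2 lowest members and at percentile 2.43, outside the bounds, without a brightness filter. NF-kB and inflammatory genes had a median of -0.07 and none past 2-fold. Wnt targets had a median of 0.13, with ZNRF3 at 1.17. The ERK output list had a median of 0.30 at percentile 94.9, with SPRY2 at 1.32, ETV5 at 1.29 and IER5 at -1.05. Its direction was not stable: the median was -0.31 without SPRY2 and ETV5 and -0.24 over all 23 named members, and it was outside the upper bound at percentile 98.2 with a gene span trend removed. TGF-beta targets had a median of 0.26, with CCN1 at 1.88 and ID2 at 1.05. In the BCL2 and caspase list, with a median of -0.24, CASP2 was at -1.61, BID at -1.43 and MCL1 at -1.06 while APAF1 was at 1.36.

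Markers of cell identity lay within the bounds in the main setting. Epithelial markers had a median of 0.05 over 22 members, with TJP1 at -1.34 and JUP at -1.24. Only 5 intestinal differentiation markers were bright enough, and their median was 0.69, inside the upper bound by a narrow margin and outside it when random lists were matched on gene span too, with AGR2 at 1.07 and CDX2 at -0.76. Over all 29 named members, most of them dim, the median was -0.10. Mesenchymal markers had 4 bright members and were not placed among random lists. Over the 27 named mesenchymal genes the range was -0.91 to 1.19. Markers of other cell types were mostly dim. Of the named genes 11 were fibroblast markers, farthest from 0 COL1A1 at 1.10, 10 were endothelial, with ENG at 1.33, and 15 were leukocyte or blood markers, with HBA1 at 2.23. The medians of INO80, Wnt target, cytosolic ribosomal, epithelial, interferon-stimulated, proteasome and histone genes, 7 lists near 0, changed sign with the scaling, within -0.15 and 0.13. Genes used as references for quantification ranged from ACTB at -1.48 to POLR2A at 1.61, with a median of -0.20. Mitochondria-encoded transcripts, meant as a sign of RNA quality, were not among the named genes.

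**Figure D3:**
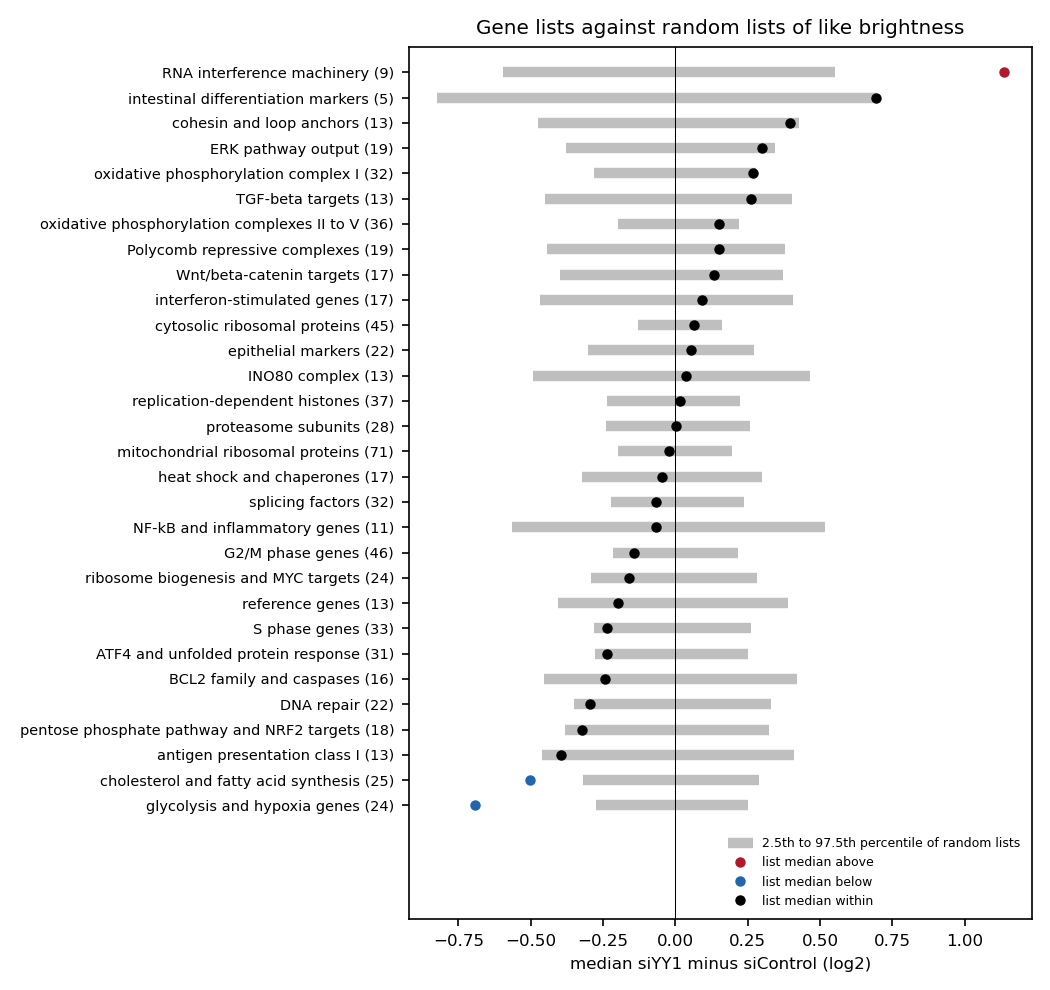
Median log2 difference (siYY1 minus siControl) of 30 gene lists, with the number of members compared in brackets, as points, and the range of 10000 random lists of the same size and brightness without the outer 2.5% on each side as grey bars. The RNA interference machinery lies above its bar at 1.13, and cholesterol and fatty acid synthesis at -0.50 and glycolysis and hypoxia genes at -0.69 lie below theirs.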

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

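The tests on large proteins, on lists of bright genes and on genes of small proteins, and those that match gene span or leave out 2 members, were chosen after the list results were seen. For the lists of bright genes and of genes of small proteins the criterion was also set afterwards, so both restate known values. Among the 3739 probe sets without a gene name, which the comparison did not use, 1332 passed the same brightness minimum, and 151 of these were at least 2-fold higher and 102 at least 2-fold lower in the siYY1 array. These are shares of 11.3% and 7.7%, against 7.9% and 9.4% of the 8747 genes compared. They were set aside for a closer look because they lie outside the comparison, and no gene can be given for them here.

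Higher levels of the RNA interference machinery were seen beside higher levels of the set of genes of large proteins. When random lists were matched on genomic span as well as brightness, the list's median of 1.13 stayed at percentile 99.86, which argues against wide genes in general as the whole cause, and without its 2 highest members it stayed at percentile 99.68. The set of genes of large proteins from outside every list was higher by a median of 0.67 over 158 genes, above all 10000 random lists. The RNA interference list lay at percentile 86.79 of lists of its size drawn from them. If large proteins stand for long messenger RNAs, a candidate explanation is that these read higher on the siYY1 array. That could come from RNA integrity or labelling, from the knockdown, or from another effect of the siRNA. No transcript lengths were measured, for this set or for the RNA interference genes, so the candidate was not tested directly. With 1 array per group, array and group cannot be told apart, and a specific response of this pathway stays an untested alternative.

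Lower glycolysis and hypoxia genes were set against 3 properties of the array. In the values as deposited, before quantile normalization, the lowest median among all 4 other lists at least as bright was -0.1467, for proteasome subunits, against -0.83 for this list, which argues against a loss of bright signal on the siYY1 array as the whole cause. Among 5 lists of genes of small proteins the lowest median was -0.0226, for mitochondrial ribosomal proteins. As far as protein size stands for messenger RNA length, which was not measured, this argues against short messenger RNAs as a class. With random lists matched on genomic span the list was at percentile 0.00, below all 10000. Among the causes that remain open are intermediate transcript lengths, culture density and oxygen supply of the single cultures, and the knockdown of YY1. The last is an untested hypothesis. Since YY1 was not read, effects of the siRNA other than on YY1 cannot be told apart from it.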

How the results depend on the processing

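No paired analysis was possible because each group holds 1 array, and no replicate could be left out. The counts of 693 higher and 820 lower genes became 365 and 381 with only genes past the 75th percentile of brightness, 1699 and 1909 at 1.5-fold, and 165 and 213 at 3-fold, as the construction of these settings implies. They stayed within 1.5 times in the other settings. Centring on medians moved the median of all genes compared by -0.10, loess by -0.02 and the values as deposited by -0.12. The number of lists outside the bounds was 3 in the main setting, 6 without a brightness filter, 5 with list means, 5 with random lists matched on gene span and 7 after removal of a gene span trend. The cause was not tested. The medians of RNA interference genes (0.81 to 1.13) and of glycolysis and hypoxia genes (-0.83 to -0.60) stayed outside the bounds in all 12 alternatives. Of these, quantile normalization only repeats the main setting, and the brightest probe set gave the same gene counts as the main setting. Cholesterol and fatty acid synthesis came inside at -0.17, both with the 75th percentile filter and without its 2 lowest members. Lists that went outside in some setting were S phase, class I antigen presentation, pentose phosphate and NRF2, DNA repair, cohesin, complex I, intestinal differentiation and ERK output. Of these S phase was at percentile 0.45 and cohesin at 98.6 with list means, complex I at 99.1 and intestinal differentiation at 98.1 with span matching, and ERK output at 98.2 with the span trend removed. Without the 2 members farthest in its direction the median of 8 of 29 lists changed sign, ERK output from 0.30 to -0.31 and the others within 0.10 of 0. Of 93 named genes 10 came under 2-fold in some setting, 1 passed it, and none changed sign. The pseudocount alternatives did not apply to log2 values, and no setting gives a value for YY1. Values near the dim end leave the size of differences such as that of CDKN1A uncertain.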

Other observations

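All gene families in this part were chosen after the values were seen. Zinc finger genes with a ZNF number, many of which encode DNA-binding repressors, lay mostly below 0. Over 241 such genes the median was -0.43, 177 were below 0, and 44 were at least 2-fold lower against 15 at least 2-fold higher. The median was -0.53 in the values as deposited. At the ends of the range were ZNF664 at -2.64 and ZNF652 at 1.97.

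Subunits of the SWI/SNF remodelling complexes, picked because of their high members, had a median of 0.41 over 22 genes, with 17 above 0, 5 below, 3 at least 2-fold higher and 1 at least 2-fold lower. SMARCA4, the ATPase, was at 2.19, ARID1A at 2.11 and ARID2 at 1.43, while BCL7A was at -1.28. Whether protein size accounts for the high members was not tested. Lysine methyltransferases and demethylases had a median of 0.26 over 28 genes, at percentile 94.5 and inside the range of random lists. Of these, 19 were above 0 and 9 below, with 8 at least 2-fold higher and 1 at least 2-fold lower. KMT2A was at 2.15, KMT2B at 2.10, KMT2C at 2.07 and KMT2D at 1.69, while KMT2E was at 0.19 and KDM5B at -1.08. The siControl value of KMT2B, 6.50, was in the range of dim genes restricted to other tissues, so the size of its difference is uncertain. The highest of these genes encode large proteins, but protein size was not compared between the higher and the lower members. All 11 genes of the NPIP family were at least 2-fold higher, from 1.55 for NPIPB3 to 2.54 for NPIPA3, and as near-identical copies they are not 11 independent measurements. Nucleoporins had a median of -0.17, between NUP43 at -1.85 and NUP214 at 2.29, and mitochondrial import genes a median of -0.02, between TIMM8A at -3.01 and TIMM9 at 1.38.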
